A study of Mus musculus with 4 samples.

How the data were processed

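The data were 4 RNA libraries from mouse dorsal root ganglia, all from the methylglyoxal group. Per the labels' protocols, total RNA was isolated with TRIzol, depleted of ribosomal RNA with a RiboCop kit and made into libraries with a Lexogen QuantSeq kit, which reads the 3′ ends of transcripts. In such libraries the reads of a transcript do not grow with its length. The submitters' processing notes list FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9 and Cufflinks 2.2.1 and the builds GRCm38.p4 and mm10, without saying which step each was used for. The annotation, the use of strand and the treatment of reads with several matches are not given in the sources used here.

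The deposited table gives 1 value per gene and library for 48431 genes. Per the file headers the values are TPM, but they behaved as CPM, read counts scaled to a common total with no scaling by gene length: at least 98.277% of the values above 0 in every library lay within 0.05 of a whole multiple of 1 step shared by all genes, and each library summed to 1000000. The deposited values were therefore used as CPM. The steps were 0.0986, 0.111, 0.179 and 0.138 CPM in replicates 1 to 4, which gives 10138768, 8975725, 5576819 and 7223783 reads if a step is 1 read. No count model was used, since some values were fractions of a step. The analysis had been planned for log2(TPM + 1), and the same steps were run on log2(CPM + 1).

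Columns were matched to samples by replicate number. Gene identifiers were looked up in GENCODE M21 (GRCm38), where 48052 (99.2%) had an entry giving position, gene type and exonic length. Gene lists (28) and families (12, with 82 genes), tests and the rule for named genes were fixed before the data were examined. The rule names a fixed set of genes, the highest and lowest member of each family, up to 3 leading members of each list and members below 1 CPM throughout, the 10 genes with the highest mean, and the 10 with the largest SD of log2(CPM + 1) among genes with a mean of at least 10 CPM. Members named beyond it, such as those shown for a pair of near-identical genes, were chosen after their values were seen. Some genes and 1 list share are not reported here.

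A gene was called detected at 1 CPM or more. List shares were sums of CPM as a percent of the library, and 2 shares were compared by an exact sign-flip test. Within each family, every pair of members with at least 1 member at a mean of 1 CPM was tested on the within-library difference of log2(CPM + 1), with limma 3.58.1 in R 4.3.3 (intercept only, moderated variance, two-sided). The p-values were adjusted by Benjamini-Hochberg over 247 pairs, and a call needed an adjusted p under 0.05. A fold between genes is on the log2(CPM + 1) scale, which understates differences of low genes. Levels and SDs of lists were ranked among 10000 random lists of the same size, the SDs with matching on expression in 20 bins. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used, and BLAST 2.17.0 for copies of ribosomal protein genes.

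Replicates 1 and 2 differed from replicates 3 and 4 in whether 3 ribosomal RNA entries were listed at 0, and the libraries were set apart as 2 pairs on that ground, whose origin is not known. The main fit counts the 4 libraries as independent. Fits with the library pair as a term and on the 2 pair means were added after seeing the data. The fit on pair means has 1 residual degree of freedom, and limma then gave every gene pair the same spread (SD 1.03 on the log2 scale), so it acts as a cut-off on the fold and cannot judge the spread of a single gene pair.

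The gene pair test was checked on 1000 simulated pairs with the depths of these libraries, 800 of them unchanged. Simulated levels were drawn from genes with a mean of at least 10 CPM, so the rates do not cover pairs with lower genes. With independent noise, the 4-library fit called 70% of 2-fold and 100% of larger ratios, and 3.14% of its calls were unchanged pairs. With noise shared within library pairs, 40.3% of its calls were unchanged pairs, against 2.4% for the fit on pair means. The latter fit recovered 34% of 2-fold, 92% of 4-fold and 100% of larger ratios. The shared noise was set from medians of squared differences over the real gene pairs, which understate the variance. Gene pairs with more noise were not covered, and the shares of calls depend on the 800 unchanged pairs chosen. The ranking of lists was tested on simulated data of 100 random and 20 shifted lists of 10 genes: 6% of the random lists reached the 95th percentile for level and 3% for variation, and 100% of the shifted lists did in both. The simulated shifts were large, so smaller ones were not covered. Simulated genes varied independently, whereas members of a real list can move together and the real libraries fell into pairs. These rates therefore do not carry over to the real lists.

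The settings varied were each replicate left out, rescaling without mitochondrially encoded genes, a pseudocount of 0.1, detection at 0.1 or 5 CPM, other filters on low values, an unmoderated variance, CPM multiplied by exonic length, quantile normalization, and random lists from all genes above 0. Multiplying by exonic length was planned for TPM, and in values without length scaling it adds weight to longer genes. Leaving out the 3 ribosomal RNA entries, dividing by exonic length, using 1 library pair alone and the SD within pairs were added after seeing the data.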

Results

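RNA was measured in dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, of male mice carrying the strain label SW. The mice had received methylglyoxal (MGO), a reactive dicarbonyl by-product of glycolysis, at 2 mg/kg by intraperitoneal injection for 6 days. The labels describe 4 libraries, all of them in this 1 group, and the series title places them in a study of metabolic neuropathy. No vehicle group was analysed here, so nothing below measures a response to MGO. The questions that the data can answer are which transcripts were abundant in these ganglia, how members of a gene family ranked within a library, and how far the 4 libraries agreed. Values are CPM, counts scaled to the same total in each library, and the low values imply 10138768, 8975725, 5576819 and 7223783 counted reads in replicates 1 to 4. A count of 3 reads, taken as the floor for a gene listed at 0, equals 0.296, 0.334, 0.538 and 0.415 CPM in the same order, and this floor covers counting error only. The labels do not say whether the libraries came from separate animals, so p-values measure the spread between these libraries, which may be technical.

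Nuclear noncoding RNAs were among the 10 highest entries, Malat1 at 44832 ± 28542 CPM (SD, n = 4; 20296 in replicates 1 and 2, 69369 in replicates 3 and 4) and Meg3 at 7764 ± 3415 CPM. The mitochondrial ribosomal RNA mt-Rnr1 had 34527 ± 12469 CPM. The chaperone gene Hsp90ab1 (8881 ± 1886 CPM), Ywhah (6548 ± 1732 CPM) and Chchd2 (5553 ± 840 CPM) were also among the 10. Gm37376, at 6593 ± 633 CPM, lies on the opposite strand inside Malat1, so its reads may belong to Malat1. Of 48431 listed genes, 12827 reached 1 CPM in all 4 libraries, 11791 of them protein-coding, and each library had 14601 ± 131 genes at that level. A further 24923 genes were listed at 0 in every library.

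The libraries fell into pairs, replicates 1 and 2 against replicates 3 and 4. Across genes, Pearson's r of log2(CPM + 1) was 0.990 between replicates 1 and 2 and 0.980 between replicates 3 and 4, but 0.876 to 0.884 between the pairs. The 3 overlapping entries of the 18S ribosomal RNA locus on chromosome 17 (Rn18s-rs5, AY036118 and Gm42418) were listed at 0 in replicates 1 and 2 and held 8.26% and 10.8% of reads in replicates 3 and 4. Of 8580 genes with a mean of at least 10 CPM, 2030 (23.7%) differed by at least 2-fold between the pairs without overlap, 1538 higher in replicates 1 and 2 and 492 higher in replicates 3 and 4. After the 3 rRNA entries were left out and the libraries rescaled, these counts were 1304 and 695. Neither of the other ways to pair the libraries parted a single gene to this extent. The median gene was lower by a log2 difference of -0.19 in replicates 3 and 4. Libraries of the same pair still differed by more than counting noise, with a median chi-square per gene of 1.48 and 1.61 where sampling alone gives 0.455, which speaks only against the same library under 2 numbers. Pair means are given for some results below, and a mean of 4 libraries can hide a split in the others.

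Pan-neuronal markers, 10 genes, summed to 1.22% ± 0.101 of reads (SD, n = 4), led by the ubiquitin hydrolase gene Uchl1 (3533 ± 417 CPM), the neurofilament gene Nefm (2025 ± 127 CPM) and the neuronal tubulin gene Tubb3 (1861 ± 362 CPM). Their share was 1.29% in replicates 1 and 2 and 1.15% in replicates 3 and 4. Of the genes of myelinating Schwann cells, the myelin basic protein gene Mbp had 2635 ± 1072 CPM and the peripheral myelin gene Pmp22 had 2136 ± 1645 CPM.

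The other neural cells gave smaller shares. Satellite glia markers held 0.154% ± 0.00827 of reads, with the apolipoprotein gene Apoe at 530 ± 273 CPM, and pan-neuronal markers exceeded them in all 4 libraries (exact sign-flip p = 0.13, two-sided, the smallest value that 4 libraries allow). Markers of large myelinated neurons held 0.214% ± 0.0836, most of it from the heavy neurofilament gene Nefh (1566 ± 695 CPM). Non-myelinating Schwann cell markers held 0.102% ± 0.0145. Markers of peptidergic nociceptors, the pain-sensing neurons that release neuropeptides, held 0.0906% ± 0.0493, and those of non-peptidergic nociceptors 0.0557% ± 0.018. The peptidergic share was the higher in 4 of 4 libraries by 0.0349 ± 0.0318 points (exact sign-flip p = 0.13), at 0.133% against 0.0712% in replicates 1 and 2 but 0.0483% against 0.0402% in replicates 3 and 4. The order turned when CPM was multiplied by exonic length, a setting planned for TPM. In values without length scaling it adds weight to longer genes, so the turn does not speak on abundance. The difference between the library pairs went with exonic length, so whether the reported order is free of length is open as well. C-fibre low-threshold mechanoreceptor markers held 0.0765% ± 0.013, led by the mechanically gated channel gene Piezo2 (689 ± 154 CPM). Markers of itch-related neurons held 0.00685% ± 0.003, led by Nts (27.9 ± 15.6 CPM).

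Markers of non-neural tissue were also found. Fibroblast markers held 0.164% ± 0.0273 of reads, led by Col1a2 (620 ± 186 CPM), and vascular markers held 0.0206% ± 0.00186. Blood markers held 0.0765% ± 0.0291, and the near-identical globin genes Hba-a1 and Hba-a2 (411 ± 275 and 143 ± 70.6 CPM) moved in opposite directions between the pairs, so that reads may be split between them. Skeletal muscle markers held 0.0698% ± 0.0245, with Acta1 at 256 ± 27.6 CPM. Macrophage markers held 0.0289% ± 0.00384, led by the complement gene C1qa (154 ± 43 CPM), and pan-neuronal markers exceeded them in all 4 libraries (exact sign-flip p = 0.13). Adipocyte markers held 0.0131% ± 0.00831 and neutrophil and mast cell markers 0.013% ± 0.0114 (0.0229% in replicates 1 and 2, 0.00322% in replicates 3 and 4). Central nervous system glia markers held 0.00158% ± 0.00045, and of these Opalin stayed below 1 CPM in all 4 libraries. T and B cell markers held 0.000144% ± 5.26e-05, and Cd4 was listed at 0 in every library.

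**Figure D1:**
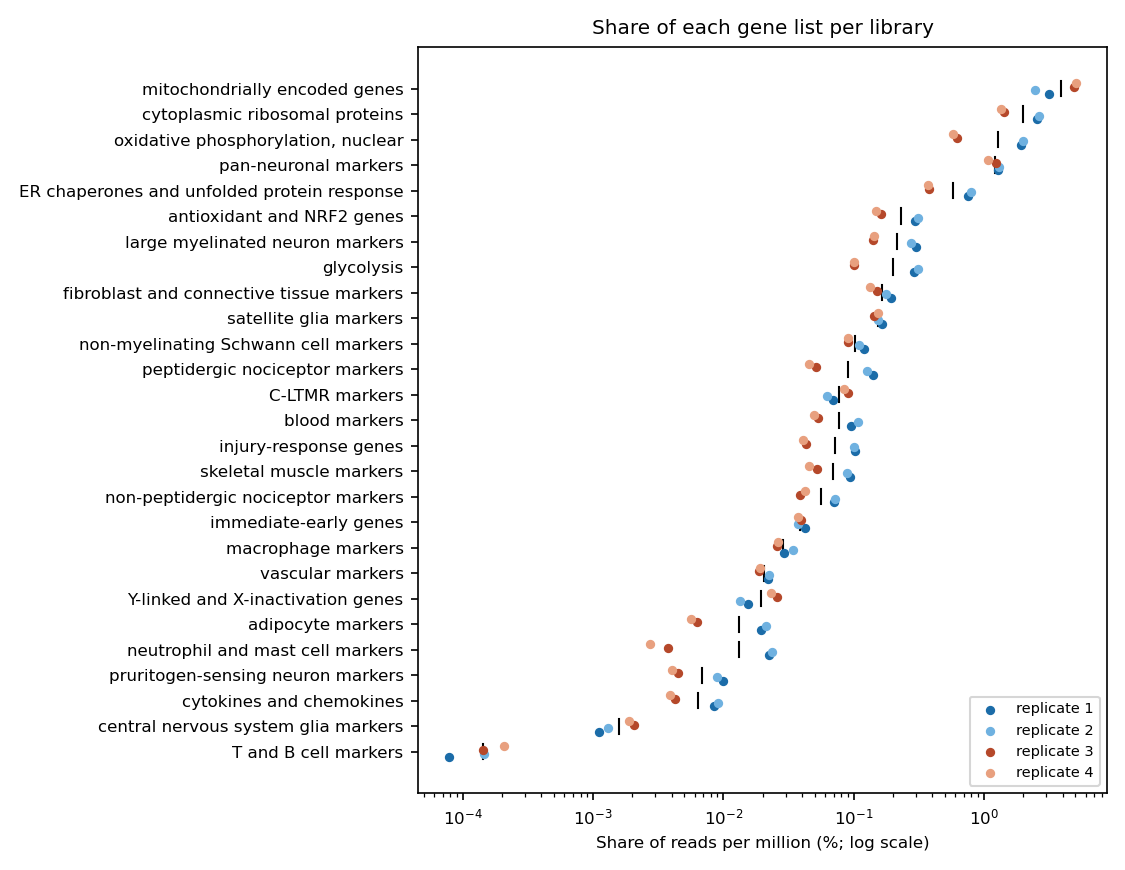
Share of reads (%, log scale) taken by each of 27 gene lists; coloured points are the 4 libraries and the black bar is their mean. Pan-neuronal markers (1.22%) lie far above satellite glia markers (0.154%), and replicates 3 and 4 lie below replicates 1 and 2 for 20 of the lists.

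Among voltage-gated sodium channels, Scn10a, which encodes the nociceptor channel Nav1.8 (chromosome 9, 119608456 to 119719322, GRCm38), was the most abundant, at 606 ± 144 CPM (SD, n = 4). Scn9a, the gene of Nav1.7 (chromosome 2, 66480080 to 66634962), had 512 ± 135 CPM, and Scn11a, the gene of Nav1.9 (chromosome 9, 119753759 to 119825456), had 201 ± 123 CPM. Scn10a exceeded Scn11a 3.48-fold (log2 difference 1.80, SE 0.31, limma adjusted p = 0.00231, higher in 4 of 4 libraries). Scn10a and Scn9a could not be ranked (log2 difference 0.25, SE 0.33, limma adjusted p = 0.498), and the order turned between the pairs: 729 against 396 CPM in replicates 1 and 2, and 483 against 627 CPM in replicates 3 and 4. Scn3a, a channel of developing neurons, had the lowest mean at 11.2 ± 1.84 CPM but could not be ranked against Scn2a1 (limma adjusted p = 0.192). The log2 difference of Scn2a1 over Scn3a was -0.27 in replicates 1 and 2 and 1.75 in replicates 3 and 4. Scn10a exceeded Scn3a 49.0-fold (log2 difference 5.61, SE 0.24, limma adjusted p = 1.14e-05).

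In the transient receptor potential family, Trpa1, the channel that reactive electrophiles open (chromosome 1, 14872648 to 14918862), had 16.2 ± 3.6 CPM, and Trpv1, the capsaicin and heat receptor (chromosome 11, 73234292 to 73261242), had 14.9 ± 7.47 CPM. They could not be ranked by limma (log2 difference 0.22, SE 0.33, adjusted p = 0.564). Trpv2 had the highest mean at 21.6 ± 11.2 CPM. Trpm8, the cold and menthol receptor, was the lowest at 2.03 ± 0.639 CPM, and Trpv2 exceeded it 6.87-fold (log2 difference 2.78, SE 0.29, limma adjusted p = 0.000271, 4 of 4 libraries).

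Calca, which encodes the neuropeptide CGRP, and Tac1, which encodes substance P, were the most abundant neuropeptide genes, at 413 ± 340 and 341 ± 75.1 CPM. They could not be ranked (log2 difference -0.20, SE 0.46, limma adjusted p = 0.706), with Calca at 706 CPM in replicates 1 and 2 and at 121 CPM in replicates 3 and 4. Calca exceeded Nppb, the neuropeptide gene with the lowest mean, 227-fold on the log2(CPM + 1) scale (limma adjusted p = 8.93e-05), with Nppb at 0 to 0.538 CPM. Nppb could not be ranked against Npy (limma adjusted p = 0.197). The log2 difference of Npy over Nppb was 1.31 in replicates 1 and 2 and -0.10 in replicates 3 and 4. Of the 27 neuropeptide pairs tested, 21 passed.

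Receptors for neurotrophic factors were led by Ret, the signalling receptor of the GDNF family (288 ± 93.2 CPM), with Gfra3 the lowest (12.2 ± 7.05 CPM). Ret exceeded Gfra3 23.9-fold (log2 difference 4.58, SE 0.24, limma adjusted p = 2.00e-05). In the family of Mrgpr and P2X receptors, P2rx4 was the highest at 85.9 ± 8.74 CPM and Mrgprb4 was listed at 0 in all libraries. P2rx3, the ATP receptor of nociceptors, had 21.2 ± 13.4 CPM and Mrgprd 10.1 ± 4.9 CPM. P2rx3 was above Mrgprd in 2 of 4 libraries only (limma adjusted p = 0.228).

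**Figure D2:**
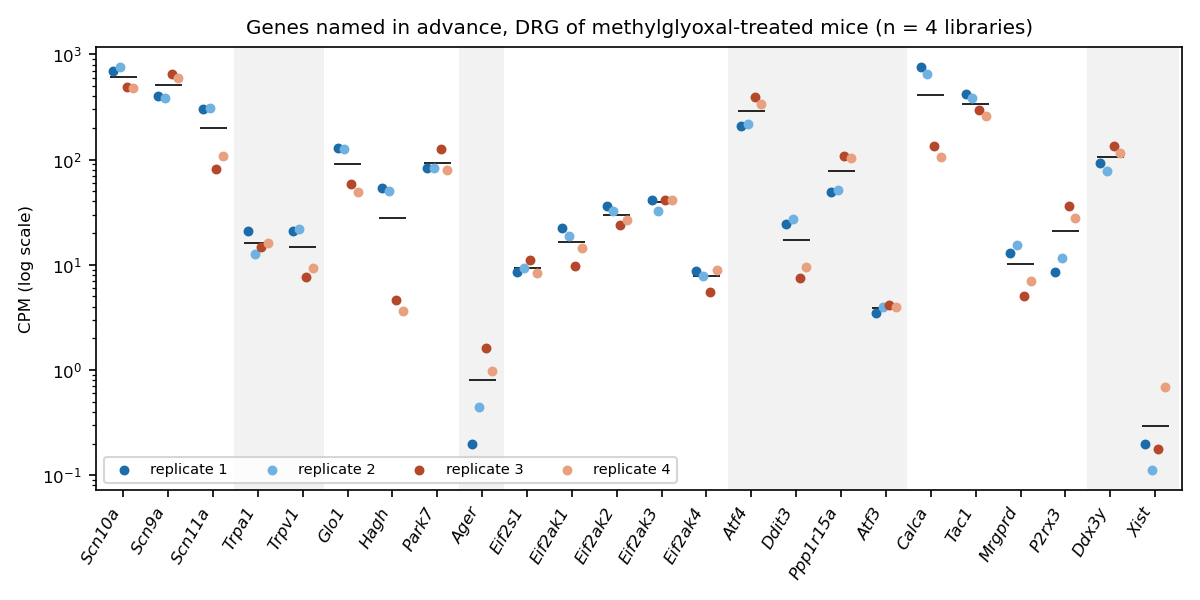
CPM (log scale) of 24 genes fixed in advance; coloured points are the 4 libraries and the black line is their mean. Scn9a and Scn10a change order between replicates 1 and 2 and replicates 3 and 4, whereas Ddx3y (105 CPM) lies far above Xist (0.295 CPM) in every library.

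Genes of MGO clearance were expressed at moderate levels. Glo1, the glyoxalase that converts the MGO-glutathione adduct (chromosome 17, 30584936 to 30626871), had 90.8 ± 42.4 CPM, and Hagh, which acts after it (chromosome 17, 24840143 to 24864450), had 28 ± 27.6 CPM. Glo1 exceeded Hagh 5.12-fold (log2 difference 2.36, SE 0.49, limma adjusted p = 0.00536) in 4 of 4 libraries, but the log2 difference was 1.28 in replicates 1 and 2 and 3.43 in replicates 3 and 4. Park7, the gene of DJ-1, had 93.4 ± 22.3 CPM and could not be ranked against Glo1 (log2 difference 0.14, SE 0.37, limma adjusted p = 0.735). Aldh2, a mitochondrial aldehyde dehydrogenase, had the highest mean at 191 ± 162 CPM, yet fell behind Park7 in replicates 3 and 4 (53.6 against 103 CPM). Akr1b3 had the lowest mean at 7.53 ± 5.31 CPM but could not be ranked against Hagh or Aldh9a1 (limma adjusted p = 0.346 and 0.189). In replicates 3 and 4 it lay above both, with log2 differences of -1.33 for Hagh over Akr1b3 and -0.58 for Aldh9a1 over Akr1b3. Of 15 pairs, 9 passed.

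Ager, which encodes the receptor for advanced glycation end products (chromosome 17, 34597862 to 34600936), was the lowest of the 5 genes for proteins that bind such products, at 0.806 ± 0.627 CPM. The 2 lower values, 0.197 and 0.446 CPM, stand for only a few reads. Ddost had the highest mean at 16.6 ± 13.1 CPM, yet fell behind Cd36 in replicates 3 and 4 (5.41 against 12.4 CPM; limma adjusted p = 0.767). It exceeded Ager 7.86-fold on the log2(CPM + 1) scale (log2 difference 2.97, SE 0.65, limma adjusted p = 0.00654, 4 of 4 libraries). The log2 difference was 4.45 in replicates 1 and 2 and 1.498 in replicates 3 and 4, and the call was lost without the moderated variance (adjusted p = 0.0573).

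Of the 4 kinases that phosphorylate eIF2α, the translation factor subunit at the centre of the integrated stress response, Eif2ak3 (PERK) was the most abundant at 39.3 ± 4.42 CPM. Eif2ak2 (PKR) followed with 29.9 ± 5.75 CPM, Eif2ak1 (HRI) with 16.3 ± 5.49 CPM and Eif2ak4 (GCN2) with 7.78 ± 1.57 CPM. Eif2ak3 exceeded Eif2ak4 4.62-fold (log2 difference 2.21, SE 0.23, limma adjusted p = 0.00025). The step from Eif2ak3 to Eif2ak2 did not pass (limma adjusted p = 0.173, 3 of 4 libraries). Eif2ak3 exceeded Eif2ak1 2.41-fold (log2 difference 1.27, SE 0.28, limma adjusted p = 0.00722) in 4 of 4 libraries, with log2 differences of 0.81 in replicates 1 and 2 and 1.73 in replicates 3 and 4. At the same log2 difference the call was lost on pair means (SE 0.73, adjusted p = 0.122), a fit that acts as a cut-off on the fold. Eif2s1, which encodes eIF2α itself, had 9.32 ± 1.25 CPM, far below Eif2s2, which had the highest mean of the eIF2 and eIF2B subunit genes at 271 ± 118 CPM but could not be ranked against Eif2b5 (limma adjusted p = 0.147, higher in 2 of 4 libraries). Eif2b1 was the lowest of these at 2.89 ± 2.08 CPM, and Eif2s2 exceeded it 73.1-fold (log2 difference 6.19, SE 0.21, limma adjusted p = 5.57e-06).

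Atf4, the transcription factor of the integrated stress response (chromosome 15, 80255184 to 80257541), led its group at 289 ± 89 CPM. Ppp1r15a, the gene of the phosphatase subunit GADD34, had 78.2 ± 32.5 CPM, Ddit3, the gene of CHOP, had 17.3 ± 10.2 CPM and Atf3 had 3.9 ± 0.303 CPM. Atf4 exceeded Ppp1r15a 3.79-fold (log2 difference 1.92, SE 0.21, limma adjusted p = 0.000294) and Ddit3 17.5-fold (log2 difference 4.13, SE 0.52, limma adjusted p = 0.000566), each in 4 of 4 libraries. Between the pairs, Atf4 and Ppp1r15a were at 215 and 50.04 CPM in replicates 1 and 2 against 364 and 106 CPM in replicates 3 and 4, while Ddit3 went from 26.0 to 8.54 CPM. Chac1, the lowest member, stayed at 0.0986 to 0.446 CPM. Of 36 pairs, 29 passed.

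Other translation factors spanned a wide range. Eef2, the ribosomal translocase, had 1545 ± 543 CPM and exceeded the gene of its inhibitory kinase, Eef2k (4.73 ± 2.43 CPM), 280-fold (log2 difference 8.13, SE 0.25, limma adjusted p = 5.57e-06). In the cap-binding group, Eif4g2 had the highest mean at 499.9 ± 91.7 CPM and Mknk2, a kinase of eIF4E, the lowest at 3.57 ± 0.429 CPM, a 109-fold difference (log2 difference 6.76, SE 0.20, limma adjusted p = 5.57e-06). Eef1a1 and Eef1b2 have near-identical copies in the mouse genome, so their levels are uncertain.

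Over all 12 families, 188 of 247 gene pairs passed at an adjusted p of 0.05 (limma, Benjamini-Hochberg), with the same direction in 4 of 4 libraries for 200 pairs and opposite directions in the library pairs for 38. With each library pair counted as 1 value, a fit chosen after seeing the data, 159 pairs passed, all of them among the 188. That fit gave every gene pair the same SE (0.73) and so acts as a cut-off on the fold, which drops the pairs with the smaller differences. The 4-library fit treats libraries of a pair as independent, and on simulated data with noise shared within pairs it called 15.1% of unchanged gene pairs. The simulated noise may be smaller than the real noise. Both fits see only the spread between libraries, so a constant difference in how reads of the genes were captured or assigned would pass too. Folds between genes therefore rank reads and not necessarily transcripts.

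Several gene groups stood high among detected genes. The median level of 13 of the 28 lists lay at or above the 95th percentile of random lists of the same size. Pan-neuronal markers (median 991 CPM) and ribosomal proteins (114 CPM) were both at percentile 100, ER chaperones (116 CPM) at 99.99, glycolysis genes (79.6 CPM) at 99.96 and antioxidant genes (76.5 CPM) at 99.94. The chaperone gene Hspa5 (BiP) had 2352 ± 1572 CPM, the glycolytic gene Pgam1 507 ± 258 CPM and the peroxiredoxin gene Prdx1 656 ± 504 CPM. Injury-response genes reached percentile 63.6, led by Vgf (227 ± 152 CPM) and Jun (154 ± 68.8 CPM). Immediate-early genes reached percentile 36.2, led by Dusp1 (212 ± 14.9 CPM) and Egr1 (73.2 ± 11.8 CPM). Cytokines and chemokines lay at percentile 3.02, where Cxcl12 had 26.2 ± 1.64 CPM and Il6 at most 0.223 CPM. Random lists were drawn from genes with a mean of at least 1 CPM, whereas list members below that were kept, which lowers their lists. That mean was reached by 6 of 10 cytokine and chemokine genes and by 7 of 10 immediate-early genes.

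Lists of energy metabolism and translation varied between the libraries. Nuclear genes of oxidative phosphorylation held 1.96% of reads in replicates 1 and 2 and 0.599% in replicates 3 and 4, and 80 of the 86 members measured were lower in the latter. The ribosomal protein share was 2.59% and 1.39%, with 74 of 79 members lower, and the glycolysis share 0.30% and 0.10%, with 14 of 15 lower. Short genes as a whole were lower in replicates 3 and 4, with a median log2 difference of -1.27 in the shortest of 20 length bins. Bins 2 and 3 were at -0.86 and -0.90. The median was -1.29 for ribosomal proteins, -1.72 for oxidative phosphorylation and -1.68 for glycolysis. The change in ribosomal proteins was thus close to that of the shortest bin only, and the lists were not matched on length. Mitochondrially encoded genes went the other way, at 2.78% and 4.97%, mostly through mt-Rnr1. An exact permutation test of 2 libraries against 2 cannot give a p below 0.333. Set against random lists matched on expression but not on length, 9 of 27 lists reached the 95th percentile of the SD between libraries, including oxidative phosphorylation and ribosomal proteins (both percentile 100), glycolysis (99.99), injury-response genes (99.6), neutrophil and mast cell markers (99.1), peptidergic nociceptor markers (98.5), antioxidant genes (97.6), adipocyte markers (96.7) and cytokines (96.7). Immediate-early genes varied little, at percentile 3.48. With the SD taken within the library pairs, added after seeing the data, 2 lists reached that percentile and none of them was among the 9.

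**Figure D3:**
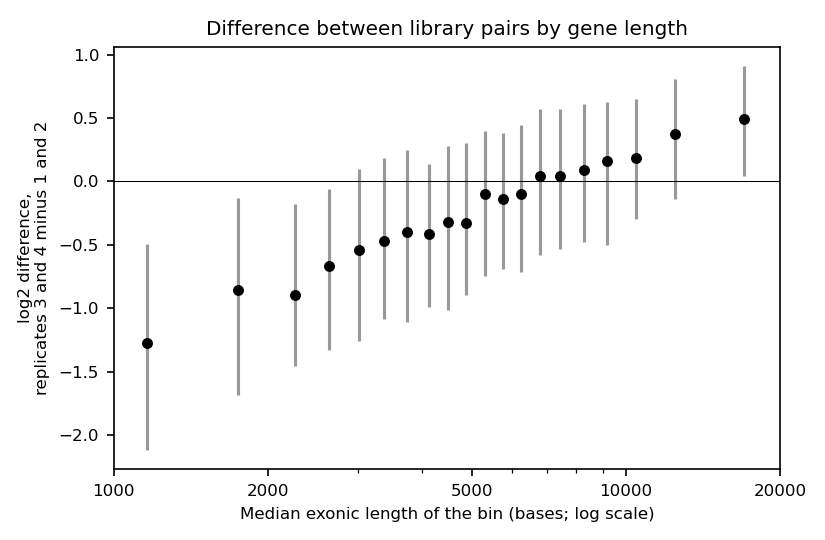
Median log2 difference between the library pairs (replicates 3 and 4 minus 1 and 2, vertical axis) in 20 bins of protein-coding genes by exonic length (bases, log scale); grey lines span the quartiles. The difference rises from negative values in the shortest genes to positive values in the longest, with a Spearman rho of 0.412 over 8264 genes.

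The sex-linked genes were read as a check of the male label. The Y-linked gene Ddx3y had 105 ± 25 CPM (SD, n = 4), Uty 40.2 ± 18.3, Eif2s3y 30.9 ± 6.41 and Kdm5d 18.2 ± 11.1 CPM. Xist, the RNA of the inactive X chromosome, lay between 0.111 and 0.692 CPM.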

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

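In this part, the tests of intron length, of GC content at fixed exonic length, of centring by exonic length and of whole steps were chosen after the values were seen. For each of 109 values with 4 libraries, the gap of the most extreme library to its neighbour was compared with the whole range (Dixon's ratio, at its 95% critical value), and 7 stood out where chance gives about 5.45 (1 in 20) for independent values. Replicate 3 was the highest for Park7 (ratio 0.916) and for Cd36 (0.877). Replicate 2 was the lowest for Eif2ak3 (0.953). Replicate 1 was the lowest for Atf3 (0.831) and the highest for Msr1 (0.931). Replicate 3 was the lowest for Trpm8 (0.979), at 1.08 CPM against 2.34 to 2.37 in the others. Replicate 4 was the highest for Xist (0.852), at 0.692 CPM. Since the libraries fall into pairs, the number expected by chance is uncertain, and no library holds most of the 7.

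The largest pattern is the split of replicates 1 and 2 from replicates 3 and 4. Transcript length goes with it: across 8264 protein-coding genes, which are not independent replicates, the log2 difference rose with exonic length (Spearman rho 0.412, 95% bootstrap interval 0.393 to 0.430), from a median of -0.85 in the shortest quartile to 0.26 in the longest. Exonic length as measured here is not the whole difference, since centring by it left 1487 genes that part the pairs against 1896 before (78.4%). It counts all annotated exons of a gene and not the transcripts expressed, so the length of those transcripts could still account for more. GC content had a rho of -0.178 (interval -0.201 to -0.159), and -0.0557 at fixed exonic length. For unspliced or nuclear RNA, the partial rho with intron length was 0.0562 at fixed exonic length (interval 0.0331 to 0.0782). Long noncoding RNAs lay 0.24 above coding genes in median log2 difference. Of 206 such RNAs, 43 were at least 2-fold higher and 41 at least 2-fold lower in replicates 3 and 4. The interval for intron length leaves out 0, and none was computed for long noncoding RNAs. The values for intron length and for long noncoding RNAs fell between the bounds set for them, so their part stays open. Gene types outside that test differed more from coding genes (median -0.21): the median was 1.28 for 54 unconfirmed entries (type TEC) and 1.72 for 15 processed pseudogenes. With the 3 ribosomal RNA entries left out and the libraries rescaled, 1999 of 8577 genes (23.3%) still differed by at least 2-fold between the pairs without overlap. Leaving out these entries rescales all genes of a library by the same factor. It therefore shows only that their share of reads does not by itself account for these differences. A difference in library preparation or in how reads were assigned to genes may underlie the rest, and a biological difference between animals stays open. The labels give nothing that separates the pairs, and none of these was tested.

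Ribosomal protein genes, whose proteins are needed in equal amounts in a ribosome, spanned 1.49 CPM (Rpl29) to 3288 CPM (Rplp1). Loss of short transcripts gained no support (rho of level with transcript length -0.0267 over 79 genes, 95% bootstrap interval -0.236 to 0.189; permutation p = 0.811), but the interval reaches past the bound of 0.1 set before, so it stays open. Reads shared with near-identical copies may contribute: level was lower for genes whose 3′ end has more copies (rho -0.255, interval -0.423 to -0.0479; permutation p = 0.0238, Benjamini-Hochberg over the 2 tests 0.0476), but the value missed the bound of -0.3 set before, so this stays open too. Rpl29 (58 other genes with a matching transcript) and Rps2 (45) were among the lowest, but Rpl21 (60) and Rpl7a (52) had 95.5 and 91.6 CPM. The median was 117 CPM for genes with no copies and 91.6 CPM for those with 10 or more. No biological explanation was tested.

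The column headers name TPM. In every library at least 98.277% of the values above 0 lay within 0.05 of a whole multiple of 1 step, which is consistent with read counts scaled to a common total, and not with division by gene length.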

How the results depend on the processing

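The alternatives that use library pairs, that leave out the 3 ribosomal RNA entries or that divide by exonic length were chosen after seeing the data. The number of detected genes stayed within 1.5 times the reported value under all 8 alternatives (8973 at 5 CPM to 16304 at 0.1 CPM; 13017 to 13232 with a replicate left out), as did the number of called gene pairs under all 14 (155 with both members at 1 CPM to 231 with the library pair as a term; 178 to 187 with a replicate left out; with CPM multiplied or divided by exonic length only 172 and 169 of the 188 calls were kept, and 3 pairs in each were called in the opposite direction) and the number of highly expressed lists under all 11 (9 to 16; 13 with any replicate left out). The number of highly variable lists was 6 to 10 under 9 alternatives (10 with any replicate left out), but fell to 2 with the SD within library pairs, which by construction removes the difference between the pairs. Multiplied by exonic length, a setting planned for TPM that here adds weight to longer genes, the pan-neuronal share was 0.699%. With a replicate left out it spanned 1.19% to 1.27%. With that multiplication 15 other list shares moved by more than their SD, among them blood markers to 0.0107%, neutrophil and mast cell markers to 0.00156%, mitochondrially encoded genes to 0.659%, ribosomal proteins to 0.629% and C-fibre mechanoreceptor markers to 0.214%, and peptidergic markers (0.0441%) fell below non-peptidergic ones (0.0518%). For the highest member of each family against the second and the lowest (23 pairs reported), 291 of 318 alternative values kept direction and call, 9 gained and 6 lost the call. With the library pair as a term, which takes out the difference between the pairs, calls were gained for Scn10a over Scn9a (limma adjusted p 0.0351), Aldh2 over Park7 (0.00249), Eif2ak3 over Eif2ak2 (0.00432), Eif2s2 over Eif2b5 (6.50e-05) and Eif4g2 over Eif4a2 (0.00016). None of these was called on pair means, a fit that acts as a cut-off on the fold. Scn10a over Scn9a, Aldh2 over Park7 and Eif2s2 over Eif2b5 had opposite directions in the library pairs. Multiplied by exonic length, calls were gained for Eif2ak3 over Eif2ak2 (limma adjusted p 0.0409), Eif2s2 over Eif2b5 (0.00432) and Eif4g2 over Eif4a2 (0.00121). Divided by it, Scn10a over Scn9a gained the call (log2 difference 0.93, limma adjusted p 0.0408). The lost calls were Ddost over Ager and Aldh2 over Akr1b3 without moderation (adjusted p 0.0573 and 0.0593), P2rx4 over P2rx3 divided by exonic length (0.0939), and Ret over Gfra2 on pair means (0.318, a fit that acts as a cut-off on the fold) and without replicate 3 (0.0674) or 4 (0.0582). The 12 that turned direction belonged to pairs that were not called, except Ret over Gfra2, and the cause was not tested. CPM multiplied by exonic length gave log2 differences of -0.43 for Scn10a over Scn9a and -0.44 for Ddost over Cd36. CPM divided by exonic length gave -0.51 for Aldh2 over Park7, -0.62 for Eif2s2 over Eif2b5, -0.28 for Eif4g2 over Eif4a2, 0.81 for Calca over Tac1 and -0.088 for Ret over Gfra2. With a replicate left out, Aldh2 over Park7 spanned -0.017 to 1.07, Ddost over Cd36 -0.25 to 0.67 and Calca over Tac1 -0.55 to 0.16. The number of genes that part the library pairs was 1487 to 2126 over 4 alternatives. Depth limits the lowest genes: at 3 reads the floor is 0.296 to 0.538 CPM, so Ager, Nppb and Chac1 rest on few reads. No paired analysis was possible because there is 1 group, with no samples to pair across groups.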

Other observations

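Among the genes that varied most between the libraries (SD of log2(CPM + 1), mean of at least 10 CPM), 2 are known from muscle. Myl3, a myosin light chain of slow and cardiac muscle (chromosome 9, 110741861 to 110769798), had 69.7 CPM in replicates 1 and 2 and 1.63 CPM in replicates 3 and 4. Itga7, an integrin of muscle, had 283 and 14.7 CPM. Nme3 had 20.1 CPM and was listed at 0 in replicates 3 and 4. Skeletal muscle markers as a group were at 0.0909% and 0.0487%, with Acta1 at 275 and 238 CPM, a much smaller difference than that of Myl3. The entries Gm22710 and 2900060B14Rik overlap on chromosome 1 and moved in opposite directions, from 227 to 0.338 CPM and from 36.7 to 2025 CPM, so the value of either entry is uncertain.

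Some injury-response genes also differed between the pairs. The neuropeptide gene Gal had 260 CPM in replicates 1 and 2 and 15.99 CPM in replicates 3 and 4, and Vgf had 359 and 96.0 CPM, while Sox11 went from 37.4 to 105 CPM and Gap43 changed little (129 and 103 CPM). Of the 10 injury-response genes, 6 were at least 2-fold lower and 1 at least 2-fold higher in replicates 3 and 4. Of 8264 protein-coding genes with a mean of at least 10 CPM, 1891 were at least 2-fold lower and 656 at least 2-fold higher. The injury-response genes were counted from a mean of 1 CPM, so the 2 sets are not filtered alike. Immediate-early genes held 0.0396% and 0.0383% of reads, the closest agreement between the pairs among the gene lists named here. The neutrophil genes S100a9 (139 and 18.9 CPM) and S100a8 (74.6 and 6.54 CPM) were lower in replicates 3 and 4.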
